A study of Ovis aries with 14 samples.

How the data were processed

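RNA-seq was carried out on perirenal adipose tissue, taken from above the left kidney of 14 near-term sheep fetuses. The fetuses fell into 4 groups according to the labels. Intrauterine growth restriction (IUGR) was produced by keeping pregnant ewes in the heat, which limits the growth of the placenta, and control ewes were kept at a moderate temperature and fed to match. Fetuses of both kinds had either a sham operation or a surgical removal of both adrenal medullae (demedullation), the main source of circulating adrenaline. The groups held 4 sham control, 4 sham IUGR, 3 demedullated control and 3 demedullated IUGR fetuses, each sample from a separate animal.

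The values used were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) that the authors deposited in a single table of 25000 gene loci. Per the labels' protocols, mRNA was selected and sequenced as paired-end Illumina libraries. Per the submitters' processing notes, Trimmomatic, TopHat2 2.0.14, Cufflinks 2.2.1 and Cuffdiff 2.2.1 were used with the sheep build Oar_v3.1, but the settings and the role of each step are not given in the sources used here. A Cufflinks value is an estimate in which a fragment that matches several loci is shared between them, so values of near-identical gene copies, of ribosomal proteins with many pseudogenes and of overlapping genes are uncertain. Some values may also be failed estimates: EEF1A1, a translation factor that every cell uses, was listed below 1 FPKM in all 14 libraries. The table had no column of a further sample. No 2 columns held identical values.

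Read counts were not used here, so the absolute depth of each library is unknown, and no counting interval was computed. The relative depth was read from the lowest 10% of values above 0 in each pair of libraries, since genes with very few fragments share 1 ratio, that of the worth of 1 fragment. That ratio closed over 364 triples of libraries with a median error of 0.03 on the log2 scale, but between 1.26% and 26.1% of the low genes of a pair lay within 0.02 of it, so whole fragments were not recovered for most genes. The relative depth of the libraries ran from 0.760 to 1.28 around a geometric mean of 1, and the deepest library was 1.69 times as deep as the shallowest.

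From the deposited FPKM, log2(FPKM + 1) was computed. A fold change on this scale understates the change of genes with low values. Loci with a mean of at least 1 FPKM over the 14 samples were tested, which left 12851 of the 18600 loci with a value above 0. Of these, 1754 carried only an Ensembl identifier and 228 spanned less than 300 bp. A linear model with 1 mean per group was fitted to all 14 samples with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. All groups thus shared 1 estimate of the spread, with 10 residual degrees of freedom and 2.82 added by the prior. The 5 comparisons were sham IUGR against sham control, demedullated IUGR against sham IUGR, demedullated control against sham control, demedullated IUGR against demedullated control, and the interaction, which is the growth restriction effect in demedullated fetuses minus that in sham fetuses. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05.

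Gene lists for adipose metabolism, hormone and stress responses, and markers of other cell types were fixed before the data were examined. Of 37 lists, 34 had at least 3 tested members. Each was tested against all other genes with camera of limma at its preset inter-gene correlation of 0.01, and again with an estimated correlation. The fry test, which asks whether the members of a list move on balance one way without reference to other genes, was run beside it. Members were also adjusted over the list alone. A list score per fetus was the mean over the members of log2(FPKM + 1) minus the mean of that gene over all fetuses. Older symbols were matched through the synonyms of a RefSeq gene table, which renamed 55 tested loci. Coordinates are those of the table on Oar_v3.1, counted from 1. No annotation of that build was used here, so exons and untranslated regions are not given.

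The genes named in the text were chosen by a rule fixed before the data were examined. In each comparison these were, among genes with a symbol that passed the threshold and whose groups did not overlap, the 12 with the largest rise and the 12 with the largest fall. Where fewer than 6 genes passed, the 6 with the smallest p were named as not passing. Up to 4 members with the smallest p were named for each list described. In addition UCP1, ADRB1, ADRB2, ADRB3, LEP, ADIPOQ, PPARG, PPARGC1A, IGF1, IGF2, INSR, SLC2A4, LPL, HSD11B1, NR3C1 and DIO2 were always named where their list was described. PPARG was listed as PPARG2, and no locus was matched to INSR. Symbols on more than 1 locus were left out. Other genes named in the closing observations were chosen after their values were seen.

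The fit was tested on simulated data with 14 libraries of the same spread over 12851 genes, in which 100 genes changed by 1 and 100 by 2 on the log2 scale. The simulated noise was independent between genes, unlike that of real genes. For sham IUGR against sham control, 62% of the smaller and 90% of the larger changes were recovered, with 2 false calls. The values were 56% and 91% for demedullated IUGR against sham IUGR, 57% and 88% for demedullated control against sham control, 62% and 91% for demedullated IUGR against demedullated control, and 35% and 78% for the interaction, with 13, 4, 11 and 9 false calls in that order.

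Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter or a minimum mean of 5 FPKM, median-of-ratios, quantile and TPM scaling, limma without a trend or with robust array weights, only the groups compared, covariates for sex, gestational age and the prefix of the animal number, removal of the single female fetus, a replicate block, an adjusted p of 0.1, the sham IUGR fetuses split 2 and 2 between the effects that share them, and each fetus left out in turn. The animal numbers begin with 11 or 12, and what the prefix stands for is not stated in the labels. All 4 sham controls had prefix 11 and all 3 demedullated controls prefix 12. Of the sham IUGR fetuses 1 had prefix 11 and 3 had prefix 12, and of the demedullated IUGR fetuses 2 had prefix 11 and 1 had prefix 12. A fit without 3 libraries that held liver transcripts, and a fit without loci under 300 bp, were added after the data were seen.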

Results

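Gene expression was measured by RNA-seq in perirenal adipose tissue, the main brown fat depot of the newborn lamb, from 14 sheep fetuses near term. Sham control fetuses weighed 3.58 ± 0.303 kg (mean ± SD, n = 4) and sham IUGR fetuses 1.28 ± 0.287 kg (n = 4). Demedullated controls weighed 3.54 ± 0.267 kg (n = 3) and demedullated IUGR fetuses 1.96 ± 0.305 kg (n = 3). Tissue was taken at 132 to 136 days of gestation, and 1 fetus, in the demedullated IUGR group, was female. The relative sequencing depth, read from the lowest FPKM values, was 1.07 ± 0.222 (SD, n = 4) in sham controls, 0.949 ± 0.136 (n = 4) in sham IUGR, 1.09 ± 0.0839 (n = 3) in demedullated controls and 0.940 ± 0.0606 (n = 3) in demedullated IUGR fetuses. The absolute depth is unknown. The sum of FPKM per library lay between 714726 and 1064128. Log2 levels of 12851 tested loci correlated between fetuses of a group with a Pearson r across genes of 0.929 to 0.957 and between fetuses of different groups with an r of 0.910 to 0.959. The tissue was rich in adipocyte transcripts: ADIPOQ (adiponectin) was at 6314 ± 658 FPKM (SD, n = 4) and UCP1, the uncoupling protein of brown fat, at 3889 ± 2652 FPKM (n = 4) in sham controls. In 3 libraries (sham IUGR 2, demedullated control 0 and demedullated IUGR 0), 23 of 30 liver transcripts lay above all 11 other libraries, such as AHSG (fetuin-A) at 1530, 244 and 202 FPKM against a median of 0.495 in the others.

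The comparison of sham IUGR with sham control fetuses asked how growth restriction alters the depot with the adrenal medulla intact. Genes of cholesterol synthesis and markers of adipose progenitors and fibroblasts, with collagen and other matrix genes, were lower in sham IUGR fetuses as lists at the preset correlation of camera, and ribosomal protein genes were higher. With an estimated correlation 0 of 34 lists passed (adjusted p = 0.505 for matrix genes and adjusted p = 0.261 for the other 3). Of single genes, 2 rose and 8 fell at an adjusted p under 0.05 in limma, but with median-of-ratios or quantile scaling it was 2 and 2, so the excess of falls depended on the scaling. PCK2 (chromosome 7, 20656653 to 20664937), the mitochondrial phosphoenolpyruvate carboxykinase, rose from 59.9 ± 11.2 to 171 ± 37.1 FPKM (SD, n = 4 each), a log2 fold change of 1.49 ± 0.20 (SE, adjusted p = 0.0207). IGFBP5 (chromosome 2, 217650010 to 217669182), a binding protein of insulin-like growth factors, fell from 162 ± 24.2 to 49.6 ± 11.4 FPKM, a log2 fold change of −1.71 ± 0.26 (adjusted p = 0.0346). AADAC (chromosome 1, 234266541 to 234289075), a microsomal esterase, fell from 23.1 ± 7.09 to 3.26 ± 1.26 FPKM, with a log2 fold change of −2.48 ± 0.33 (adjusted p = 0.0207).

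Another 5 named genes fell. MATN4 (chromosome 13, 73137854 to 73150151), which encodes the matrix protein matrilin-4, had a log2 fold change of −1.38 ± 0.18 (SE), and MRC2 (chromosome 11, 46503733 to 46528230), a receptor for collagen uptake, one of −1.41 ± 0.22. ALOX15 (chromosome 11, 26321704 to 26328096), a lipoxygenase, changed by −2.11 ± 0.34, PLXDC1 (chromosome 11, 39167905 to 39232402), a plexin domain receptor, by −1.36 ± 0.20, and TP53INP2 (chromosome 13, 63611686 to 63612601), a regulator of autophagy, by −1.24 ± 0.20. Their adjusted p-values lay between 0.0207 and 0.0386. The remaining 2 loci carried only Ensembl identifiers: ENSOARG00000015337 rose (log2 fold change 1.89) and ENSOARG00000017632 fell (log2 fold change −1.24). At an adjusted p under 0.1, 199 genes passed, 30 higher and 169 lower (33 and 54 with median-of-ratios scaling, 23 and 45 with quantile and 21 and 112 with TPM scaling), and 1944 genes had an unadjusted p under 0.05, where 643 would be expected by chance. Genes vary together, so counts far from 643 also arise by chance: another split of the same sham fetuses gave 2302. The median gene was lower by a small amount (log2 −0.07), so changes here stand beside that shift.

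The 10 calls rested on few fetuses. Without sham control 0, sham control 3, sham IUGR 0 or sham IUGR 1, 0 genes passed in limma, and without sham control 2 it was 1 gene. Without sham control 1 the count rose to 234. It was 17 without sham IUGR 3, 21 without demedullated control 0, 3 without demedullated IUGR 0, 35 without demedullated IUGR 1 and 16 without demedullated IUGR 2. With any 1 fetus left out the log2 fold change lay between 1.37 and 1.63 for PCK2, −2.72 and −2.35 for AADAC, −1.80 and −1.52 for IGFBP5, −1.46 and −1.29 for MATN4 and −2.33 and −1.87 for ALOX15, with adjusted p-values up to 0.185. With the animal number prefix as a covariate 0 genes passed, as the SE grew. PCK2 was then at 1.45 ± 0.28 (SE), AADAC at −2.34 ± 0.46, IGFBP5 at −1.66 ± 0.36, MATN4 at −1.31 ± 0.25 and ALOX15, which moved most, at −1.44 ± 0.37 (adjusted p from 0.177 to 0.268). Without the 3 libraries that held liver transcripts, with fewer samples, 0 passed, with PCK2 at 1.63 ± 0.20, AADAC at −2.46 ± 0.36, IGFBP5 at −1.78 ± 0.30 and MATN4 at −1.46 ± 0.21 (adjusted p from 0.0623 to 0.0726). Against the 4 sham controls, all of prefix 11, the 1 sham IUGR fetus of that prefix differed by log2 1.57 in PCK2, −2.26 in IGFBP5, −2.60 in AADAC and −1.57 in MATN4. These genes were named only if the groups did not overlap, so the direction in this fetus was fixed by the choice. It says nothing on the part of the prefix.

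**Figure D1:**
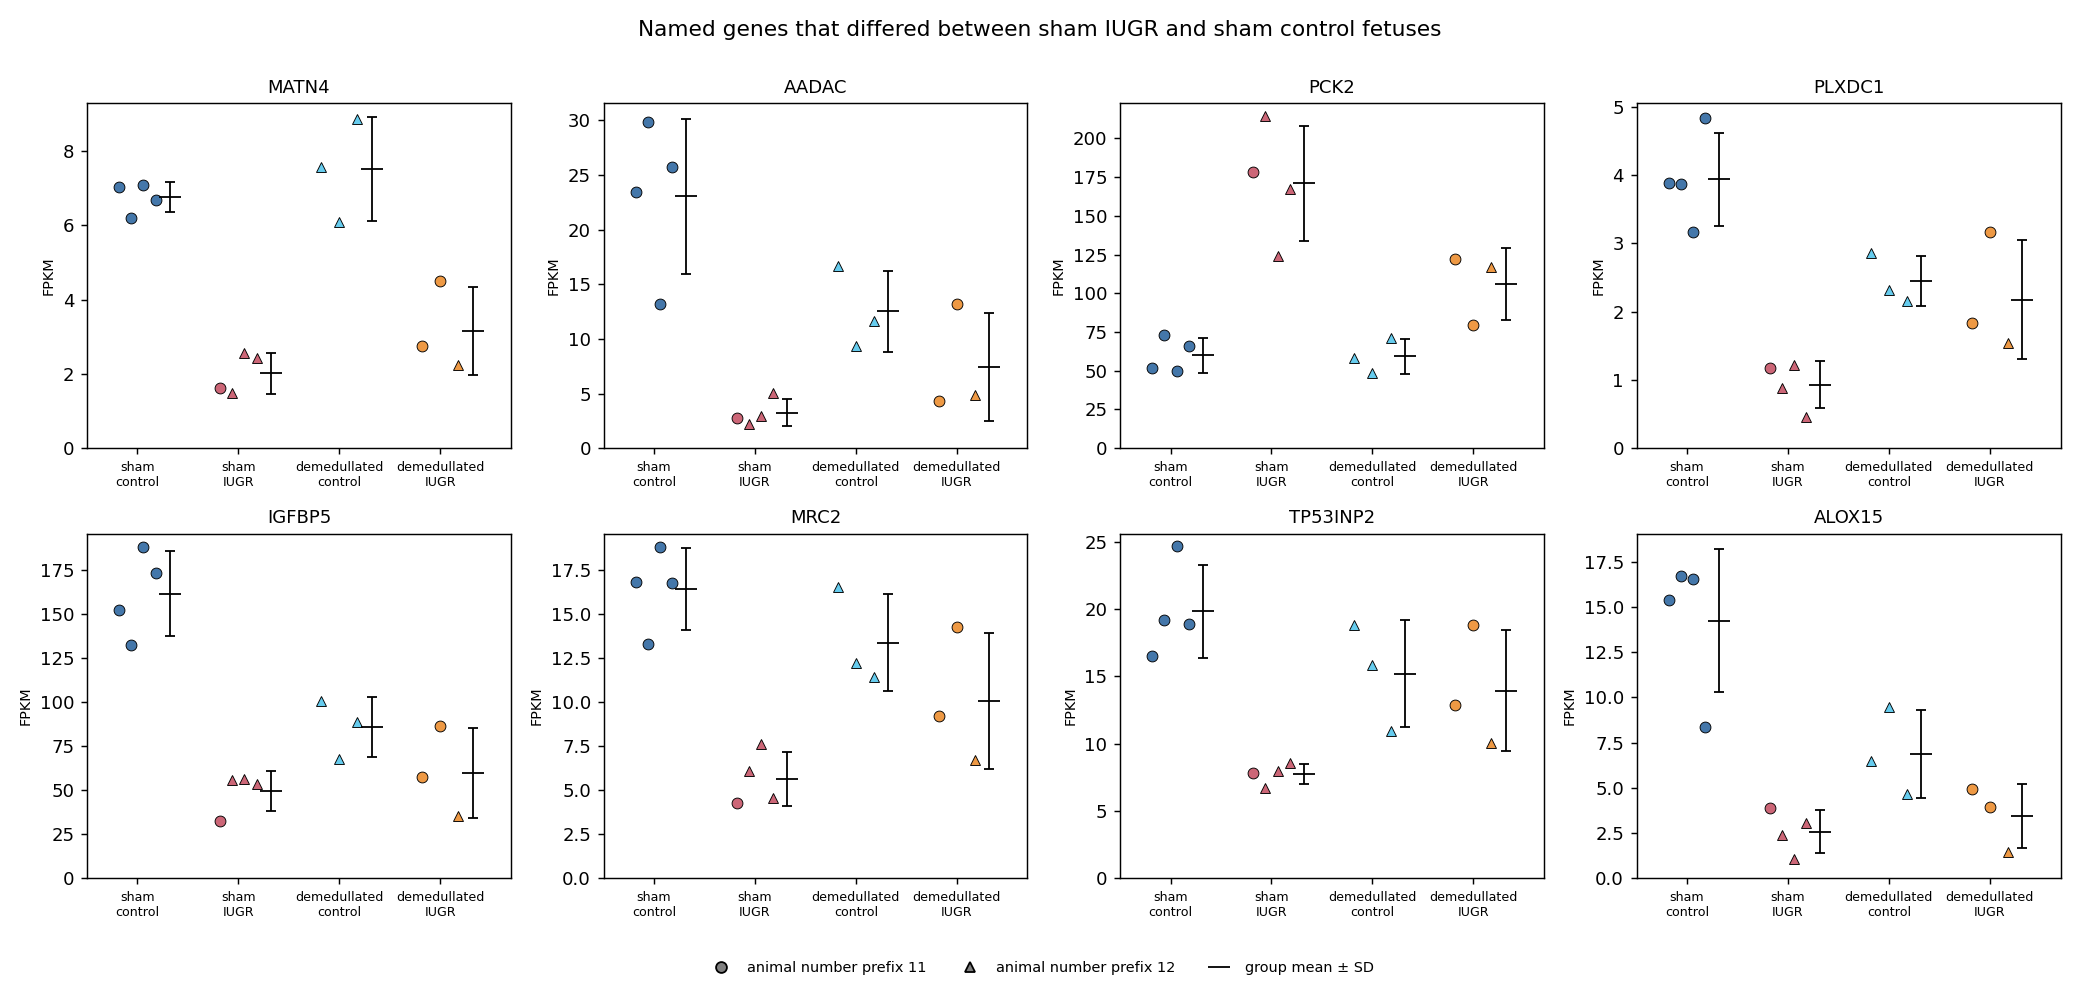
FPKM (linear axis from 0) per fetus of the 8 named genes that differed between sham IUGR and sham control fetuses, in the 4 groups, with the mean ± SD of each group as bars and the animal number prefix as the symbol. Genes were named only if the 4 sham IUGR values lay outside the range of the 4 sham controls, so that separation was fixed by the choice. PCK2 was at 171 FPKM against 59.9 on average.

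Cholesterol synthesis genes fell together in sham IUGR fetuses. All 19 measured members had a lower mean, 16 of them past the threshold when adjusted over the list alone and 0 when adjusted over all genes, and the median log2 fold change was −0.71 (adjusted p = 3.15e-12 in camera, and adjusted p = 0.261 with an estimated correlation). SREBF2, the transcription factor that drives sterol synthesis, went from 73.9 ± 8.31 to 44.7 ± 5.06 FPKM (SD, n = 4 each), a log2 fold change of −0.71 ± 0.13 (SE). LSS, which forms lanosterol, had a log2 fold change of −1.31 ± 0.24, MSMO1, a later enzyme of the pathway, −1.27 ± 0.24, and DHCR7, the enzyme of the last step, −1.36 ± 0.27. The count of 16 was 9 without sham control 1 or without sham IUGR 1, and 4 with the prefix as a covariate. The mean of the list differed by −0.80 over all fetuses and by −0.52 between the sham IUGR fetus of prefix 11 and the controls.

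Markers of adipose progenitors and fibroblasts fell in sham IUGR fetuses, 13 of 16 when adjusted over the list alone and 0 over all genes, with a median log2 fold change of −0.92 (adjusted p = 3.27e-10 in camera, and adjusted p = 0.261 with an estimated correlation). SFRP2, a secreted modulator of Wnt signalling, had a log2 fold change of −3.08 ± 0.55 (SE), COL3A1 (type III collagen) −1.27 ± 0.23, PI16, a marker of adventitial progenitors, −1.52 ± 0.31 and CD248, a stromal cell surface protein, −1.01 ± 0.22. Not every marker fell alike: DPP4 was at 0.952 to 5.29 FPKM in sham IUGR fetuses and at 1.22 to 1.94 in sham controls. DPT was at 25.6 to 44.6 and at 29.6 to 51.0 FPKM. PDGFRA, a gene of the fixed list, was not among the tested members. The mean of the list differed by −0.96 over all fetuses and by −1.24 within prefix 11. Of 33 extracellular matrix genes, 13 fell when adjusted over the list alone, with a median log2 fold change of −0.46 (adjusted p = 2.31e-05 in camera, and adjusted p = 0.505 with an estimated correlation). Among them COL1A2 had a log2 fold change of −1.75 ± 0.34, COL1A1 −1.54 ± 0.35 and LUM (lumican) −0.96 ± 0.21, and COL3A1, LUM, COL1A1, FBN1 and DCN stand in both lists. Without sham IUGR 3 the matrix median moved to −0.27. The matrix count was 5 without sham control 0, 8 without sham control 2 and 6 with the prefix as a covariate, of which 5 were lower and 1 higher. Endothelial markers had a median log2 fold change of −0.11 (adjusted p = 0.684), smooth muscle markers of 0.13 (adjusted p = 0.237) and Schwann cell markers of −0.19 (adjusted p = 0.145).

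Ribosomal protein genes rose, 14 of 23 when adjusted over the list alone, with all 23 higher in the mean and a median log2 fold change of 0.39 (adjusted p = 4.71e-16 in camera, and adjusted p = 0.261 with an estimated correlation). The smallest p-values belonged to RPS18 (log2 fold change 0.97 ± 0.21, SE), RPL8 (0.60 ± 0.16), RPS14 (0.45 ± 0.13) and RPS10 (0.48 ± 0.14), genes whose reads can be shared with processed pseudogenes. The count was 1 without sham control 2 or sham IUGR 0, 4 without sham IUGR 1, 2 with quantile or TPM scaling and 7 with the replicate block. It was 0 with no filter, with the prefix as a covariate or without the 3 libraries with liver transcripts.

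**Figure D2:**
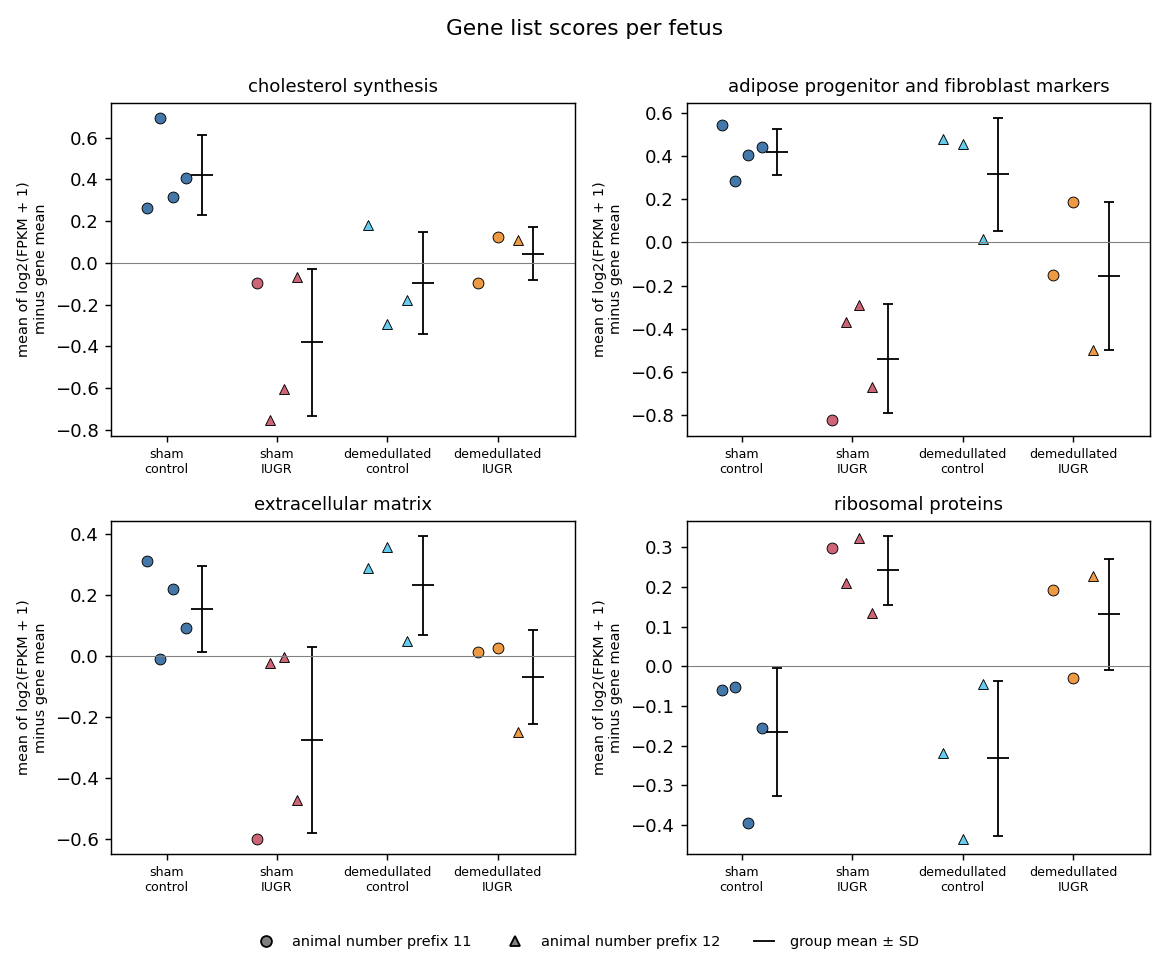
List score per fetus (mean over the members of log2(FPKM + 1) minus the gene's mean over all fetuses) for 4 gene lists, in the 4 groups, with the mean ± SD of each group as bars and the animal number prefix as the symbol. The 4 sham IUGR fetuses lie below the 4 sham controls for cholesterol synthesis (list mean difference −0.80) and for progenitor and fibroblast markers (−0.96), and above them for ribosomal proteins.

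A further 9 lists passed in this comparison, all upward. Over all 13 lists the balance was 10 upward and 3 downward. It was 6 and 3 with median-of-ratios, 5 and 4 with quantile and 12 and 3 with TPM scaling, and 7 and 5 with the prefix as a covariate. Hypoxia response genes had a median log2 fold change of 0.53 (adjusted p = 2.32e-07 in camera, and adjusted p = 0.505 with an estimated correlation) and glycolysis genes one of 0.45 (6.95e-05, and adjusted p = 0.505 with an estimated correlation), with 0 members of either past the threshold alone. Their leading members were PFKFB4, a regulator of glycolysis (log2 fold change 2.21 ± 0.68, SE), MXI1 (0.52 ± 0.16) and VEGFA, the vascular growth factor (0.53 ± 0.20). Of 19 glucocorticoid response genes, 2 rose when adjusted over the list alone, GPX3, a secreted glutathione peroxidase (log2 fold change 2.29 ± 0.60), and DUSP1, a phosphatase of MAP kinases (1.09 ± 0.29), with an adjusted p of 0.0297 for the list and an adjusted p of 0.505 with an estimated correlation. The heat shock and oxidative stress list (adjusted p = 0.000785, and adjusted p = 0.505 with an estimated correlation) also held GPX3 as its only member past the threshold alone. Oxidative phosphorylation genes (median log2 fold change 0.10, adjusted p = 0.000438) and unfolded protein response genes (0.20, adjusted p = 0.0017) had 0 members past the threshold alone, with an adjusted p = 0.754 and an adjusted p = 0.527 with an estimated correlation. So had macrophage markers (0.34, adjusted p = 0.0148) and erythroid markers (0.45, adjusted p = 0.0297), with an adjusted p = 0.715 and an adjusted p = 0.527 with an estimated correlation. With quantile scaling the median of the oxidative phosphorylation list turned to −0.03. Of the 13 list calls in this comparison, 7 held with each fetus left out: cholesterol synthesis, progenitor markers, matrix, ribosomal protein, hypoxia, glycolysis and heat shock genes. The medians without a fetus are in brackets, and those that moved did so by over 1.5 times. Without sham control 0 calls ended for glucocorticoid response (0.12) and erythroid markers (0.61), and medians moved for oxidative phosphorylation (0.06). Without sham control 1 medians moved for oxidative phosphorylation (0.19) and heat shock (0.33). Without sham control 2 calls ended for oxidative phosphorylation (−0.01) and glucocorticoid response (0.07), and medians moved for heat shock (0.05). Without sham control 3 calls ended for macrophage markers (0.07) and erythroid markers (0.22), and medians moved for the unfolded protein response (0.10). Without sham IUGR 0 the call ended for erythroid markers (0.30), and medians moved for oxidative phosphorylation (0.05), glucocorticoid response (0.04) and heat shock (0.08). Without sham IUGR 1 calls ended for glucocorticoid response (0.07) and macrophage markers (0.30), and medians moved for oxidative phosphorylation (0.15), heat shock (0.22) and erythroid markers (0.19). Without sham IUGR 2 calls ended for the unfolded protein response (−0.0001) and erythroid markers (0.48), and medians moved for oxidative phosphorylation (0.16), heat shock (0.22) and macrophage markers (0.56). Without sham IUGR 3 the call ended for macrophage markers (0.12), and medians moved for oxidative phosphorylation (0.0036) and erythroid markers (0.77).

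The thermogenic list passed as a whole (median log2 fold change 0.18, adjusted p = 0.0217, and adjusted p = 0.505 with an estimated correlation), with 9 of 16 members higher and 0 past the threshold alone. The call ended without sham control 2 (median 0.02) or sham IUGR 0 (0.10), and the median was 0.34 without sham control 1 and 0.28 without sham IUGR 2. SLC27A2, a fatty acid transporter, had a log2 fold change of 1.34 ± 0.40 (SE) and ELOVL3, a fatty acid elongase of brown fat, one of 1.21 ± 0.50. UCP1 was at 4388 ± 1237 FPKM in sham IUGR against 3889 ± 2652 in sham control fetuses (SD, n = 4 each, adjusted p = 0.853), and DIO2, which activates thyroid hormone, at 37.8 ± 32.4 against 46.7 ± 15.9 FPKM (adjusted p = 0.650). PPARGC1A, a coactivator of mitochondrial genes, had a log2 fold change of 0.56 ± 0.29 and PPARG2, the adipocyte regulator PPARγ, one of 0.44 ± 0.21, neither past the threshold. Adrenergic receptor signalling genes did not pass (adjusted p = 0.707). The adrenoceptors ADRB1, ADRB2 and ADRB3 had log2 fold changes of −0.81 ± 0.31, −0.70 ± 0.27 and −0.21 ± 0.19 (adjusted p = 0.237, 0.245 and 0.632). Insulin and IGF signalling genes did not pass as a list (adjusted p = 0.536). Besides IGFBP5, GRB14, an adaptor that inhibits the insulin receptor, fell over the list alone (−1.59 ± 0.38), with IGF1 at 0.34 ± 0.65, IGF2 at −0.19 ± 0.30 and the glucose transporter SLC2A4 at −0.08 ± 0.21. The adipocyte genes ADIPOQ, LEP (leptin) and LPL (lipoprotein lipase) differed by −0.18 ± 0.16, −0.34 ± 0.52 and −0.06 ± 0.33, and the glucocorticoid genes NR3C1 and HSD11B1 by −0.22 ± 0.18 and −0.18 ± 0.44, with no adjusted p under the threshold.

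Some lists that did not pass as a whole held single members that passed when adjusted over the list alone. Of 18 immediate early genes (list adjusted p = 0.0565) 7 did: ZFP36, MYC, DUSP1 and C-FOS were higher (log2 fold changes 0.72 ± 0.17, 0.93 ± 0.24, 1.09 ± 0.29 and 1.11 ± 0.36, SE), and EGR3, IER5 and BTG2 were lower (−1.01 ± 0.25, −1.52 ± 0.44 and −0.67 ± 0.22). Of 23 genes of fatty acid and triglyceride synthesis (list adjusted p = 0.452), THRSP, a thyroid hormone responsive lipogenic gene (−2.03 ± 0.48), FADS1, a fatty acid desaturase (−0.86 ± 0.24), and INSIG1, which restrains sterol synthesis (−0.91 ± 0.28), fell and SREBF1 rose (0.52 ± 0.15). ZNF423 and DLK1, regulators of preadipocytes, fell over the adipocyte differentiation list (−0.59 ± 0.12 and −0.80 ± 0.22). That list had a median of −0.07 and a mean of 0.06, and its test was upward (adjusted p = 0.452). In the thyroid list HR fell as well as THRSP (−0.96 ± 0.26, list adjusted p = 0.201). RGS5, a pericyte gene, fell over the smooth muscle list (adjusted p over all genes 0.0704), and STAR rose over the adrenal cortex list (2.34 ± 0.75, list adjusted p = 0.452).

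Demedullated and sham IUGR fetuses were compared. The latter weighed less (mean 1.28 against 1.96 kg), so the operation and milder restriction cannot be told apart. At the preset correlation of camera 16 lists passed, and 3 of these calls held with each fetus left out: cholesterol synthesis and interferon genes were higher in demedullated IUGR fetuses and heat shock genes lower. Without demedullated IUGR 2 the interferon median went from 1.14 to 0.49. With an estimated correlation 0 of 34 lists passed (adjusted p = 0.595 for these 3). The sham IUGR libraries stand in this and the preceding comparison, so opposite signs in the 2 are not independent. No single gene passed (0 of 12851 in limma, 805 with an unadjusted p under 0.05 against 643 expected, smallest adjusted p 0.0906). Another split of the same fetuses gave 1498 genes at that unadjusted p. The 6 named genes with the smallest p, none passing, were KLK10, a kallikrein-type protease (8.86 ± 2.29 FPKM in sham IUGR, n = 4, and 1.31 ± 1.36 in demedullated IUGR, n = 3, SD), EXOC3L2 (4.00 ± 0.577 and 9.45 ± 0.352 FPKM), PTPRK (3.91 ± 0.538 and 6.73 ± 0.411 FPKM), MPDZ (4.03 ± 0.468 and 6.70 ± 1.05 FPKM), GLUL (glutamine synthetase, 158 ± 39.4 and 75.0 ± 7.34 FPKM) and CRYM, a thyroid hormone binding protein (10.3 ± 7.71 and 1.03 ± 0.209 FPKM).

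Of 34 lists, 16 passed camera, 5 upward and 11 downward. The balance was 6 and 11 with median-of-ratios and 5 and 11 with TPM scaling, but 5 and 5 with quantile scaling and 7 and 5 with the prefix as a covariate. Cholesterol synthesis genes had a median log2 fold change of 0.40, with all 19 higher (adjusted p = 4.72e-07, and adjusted p = 0.595 with an estimated correlation), led by MSMO1 (0.90 ± 0.26, SE) and SREBF2 (0.40 ± 0.14). Progenitor markers had a median of 0.36 (adjusted p = 0.000949, and adjusted p = 0.595 with an estimated correlation), led by SFRP2 (1.66 ± 0.59) and LUM (0.56 ± 0.22). Matrix genes had a median of 0.22 (adjusted p = 0.00329), led by SPARC (0.39 ± 0.14), and endothelial markers one of 0.21 (adjusted p = 0.0159), led by MMRN2 (0.43 ± 0.17), each with an adjusted p = 0.643 with an estimated correlation. Within prefix 11 the progenitor list mean differed by 0.84 and within prefix 12 by −0.06, that of matrix genes by 0.62 and −0.08, and that of cholesterol synthesis by 0.11 and 0.58. Interferon response genes had a median of 1.14, all 20 higher (adjusted p = 1.92e-09, and adjusted p = 0.595 with an estimated correlation), with IFIT1 at 2.01 ± 0.63 and RSAD2 at 2.16 ± 0.74. Their list score was 2.10 in demedullated IUGR 2, 0.15 in demedullated IUGR 1 and 0.01 in demedullated IUGR 0, and from −1.19 to 0.47 in the sham IUGR fetuses. The medians without a fetus are in brackets, and those that moved did so by over 1.5 times. Without sham IUGR 0 calls ended for matrix genes (0.13) and endothelial markers (0.16). Without sham IUGR 3 calls ended for matrix genes (0.16) and endothelial markers (0.19). Without demedullated IUGR 0 the call ended for endothelial markers (0.22), and medians moved for matrix genes (0.13). Without demedullated IUGR 1 the call ended for progenitor markers (0.19). Without demedullated IUGR 2 the call ended for endothelial markers (0.16), and medians moved for interferon genes (0.49) and progenitor markers (0.57).

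Downward were oxidative phosphorylation genes (median log2 fold change −0.21, 49 of 53 lower, adjusted p = 7.75e-05) and TCA cycle genes (−0.31, adjusted p = 0.00134), led by CS, citrate synthase (−0.62 ± 0.31, SE). Fatty acid oxidation genes (−0.17, adjusted p = 0.0122) and glycolysis genes (−0.24, adjusted p = 0.0212) were downward too. Each of these 4 lists had an adjusted p = 0.643 with an estimated correlation, and lipolysis genes (−0.15, adjusted p = 0.0159) had an adjusted p = 0.595 with an estimated correlation. The oxidative phosphorylation mean differed by −0.35 within prefix 11 and by 0.03 within prefix 12, again with a single fetus on 1 side of each. In the fatty acid oxidation list the smallest p belonged to CPT1A, which was higher (0.69 ± 0.20). NPR3, a natriuretic peptide receptor, fell when adjusted over the lipolysis list alone (−1.05 ± 0.27). The glucocorticoid list was lower (median −0.10, adjusted p = 0.0167, with an estimated correlation adjusted p = 0.595), with GLUL past the threshold over the list alone (−1.04 ± 0.23). Heat shock genes (−0.31, adjusted p = 9.56e-05, and adjusted p = 0.595 with an estimated correlation) and ribosomal protein genes (−0.09, adjusted p = 0.0273, and adjusted p = 0.715 with an estimated correlation) had 0 members past the threshold alone. So had unfolded protein response genes (−0.17, adjusted p = 0.0122) and lymphocyte markers (−0.62, adjusted p = 0.00329), each with an adjusted p = 0.643 with an estimated correlation. In lists that did not pass, ZNF423 rose over the adipocyte differentiation list (0.53 ± 0.13) and MPZ fell over the Schwann cell list (−0.86 ± 0.24). CCL5, a chemokine, fell over the inflammatory list (−2.50 ± 0.66). Of 3 adrenal cortex markers, STAR, which carries cholesterol into mitochondria, fell over the list alone (log2 fold change −2.45 ± 0.81, with list adjusted p = 0.0466 and adjusted p = 0.595 with an estimated correlation). STAR was at 141 and 103 FPKM in sham IUGR 0 and sham IUGR 3 and at 16.5 and 8.17 FPKM in sham IUGR 1 and sham IUGR 2. That list call held only without sham IUGR 2 (−0.30) or a demedullated control and ended without any of the other 10 fetuses (−0.25 to −0.12). The medians without a fetus are in brackets, and those that moved did so by over 1.5 times. Without sham IUGR 0 the call ended for ribosomal proteins (−0.07). Without sham IUGR 1 calls ended for glycolysis (−0.14), glucocorticoid response (−0.09) and ribosomal proteins (−0.08), and medians moved for the unfolded protein response (−0.26) and lymphocyte markers (−0.37). Without sham IUGR 2 calls ended for the unfolded protein response (−0.01) and ribosomal proteins (−0.08), and medians moved for fatty acid oxidation (−0.31) and glucocorticoid response (−0.30). Without sham IUGR 3 the call ended for fatty acid oxidation (−0.09), and medians moved for glucocorticoid response (−0.25). Without demedullated IUGR 0 calls ended for lipolysis (−0.17), the unfolded protein response (−0.17), ribosomal proteins (−0.11) and lymphocyte markers (−0.42), and medians moved for oxidative phosphorylation (−0.32) and glucocorticoid response (−0.37). Without demedullated IUGR 1 calls ended for fatty acid oxidation (−0.07), TCA cycle (−0.11), oxidative phosphorylation (0.03), glycolysis (0.07), glucocorticoid response (−0.03) and ribosomal proteins (−0.06). Without demedullated IUGR 2 the call ended for glucocorticoid response (−0.07), and medians moved for lipolysis (−0.28), fatty acid oxidation (−0.31), oxidative phosphorylation (−0.33) and glycolysis (−0.38). The number of lists was 10 without demedullated IUGR 0. Thermogenic genes did not pass (adjusted p = 0.0583), and UCP1 was at 4163 ± 3835 FPKM (SD, n = 3) in demedullated IUGR fetuses (adjusted p = 0.874). Adrenergic signalling did not pass (adjusted p = 0.940).

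The comparison of demedullated with sham controls asked what removal of the medulla does in normally grown fetuses. At the preset correlation of camera, immediate early genes and endothelial markers were higher as lists in demedullated controls, and oxidative phosphorylation, TCA cycle and cholesterol synthesis genes were lower. These 5 of 12 list calls held with each fetus left out. With an estimated correlation 0 of 34 lists passed (adjusted p = 0.104 for immediate early genes, adjusted p = 0.554 for endothelial markers and adjusted p = 0.734 for the other 3). All 4 sham controls carried animal number prefix 11 and all 3 demedullated controls prefix 12, so the operation and the prefix cannot be told apart within these groups. No gene passed (0 of 12851 in limma). At an unadjusted p under 0.05 there were 897 genes against 643 expected, and up to 1702 in another split of the same fetuses. Of the 897 genes, 173 were higher and 724 lower. The direction of that imbalance depended on the scaling, as the median gene lay at log2 −0.09: it was 355 higher and 389 lower with median-of-ratios, 408 and 431 with quantile and 502 and 231 with TPM scaling, where the median gene lay at 0.09. The 6 genes with the smallest p, none passing, were C-FOS, an immediate early transcription factor (10.3 ± 3.28 FPKM in sham controls, n = 4, and 52.6 ± 13.2 in demedullated controls, n = 3, SD), HIST1H4H (log2 fold change 0.95 ± 0.19, SE), CHN1 (2.52 ± 0.170 and 5.33 ± 0.917 FPKM), GFPT2 (22.6 ± 4.32 and 11.9 ± 3.17 FPKM), the chloride transporter CLCN3 (17.4 ± 1.62 and 11.4 ± 1.56 FPKM) and ADHFE1 (19.9 ± 3.26 and 11.2 ± 3.55 FPKM).

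Of the 12 lists that passed camera, 6 were upward and 6 downward. The balance was 4 and 6 with median-of-ratios, 6 and 6 with quantile and 3 and 6 with TPM scaling. It was 1 and 7 with the prefix as a covariate and 9 and 5 without the 3 libraries with liver transcripts. Of 18 immediate early genes, 6 rose when adjusted over the list alone (list adjusted p = 4.28e-06, and adjusted p = 0.104 with an estimated correlation), with a log2 fold change of 2.27 ± 0.39 (SE) for C-FOS, 1.43 ± 0.40 for EGR1, 1.06 ± 0.31 for DUSP1 and 1.13 ± 0.35 for NR4A1. That count was 1 without sham control 0, demedullated control 1 or demedullated control 2, and 0 with the prefix as a covariate. Cholesterol synthesis genes (median log2 fold change −0.56, adjusted p = 5.72e-07) and oxidative phosphorylation genes (−0.37, adjusted p = 5.72e-07) were downward. So were TCA cycle genes (−0.35, all 19 lower, adjusted p = 1.51e-05) and fatty acid oxidation genes (−0.39, 22 of 23 lower, adjusted p = 0.00377). Each of these 4 lists had an adjusted p = 0.734 with an estimated correlation and 0 members past the threshold alone. Leading members were SREBF2 (−0.47 ± 0.14), ATP5G3, a subunit of ATP synthase (−0.61 ± 0.21), OGDH (−0.77 ± 0.24) and CPT2 (−0.52 ± 0.18). Thyroid axis genes (−0.26, adjusted p = 0.0498, with an estimated correlation adjusted p = 0.734) were led by DIO2, at 16.0 ± 14.2 FPKM in demedullated controls and 46.7 ± 15.9 in sham controls (SD, log2 fold change −1.73 ± 0.56, adjusted p over all genes 0.684). Lymphocyte markers were lower (median −0.70, adjusted p = 0.0343, with an estimated correlation adjusted p = 0.881), and their list median was −0.03 with gestational age as a covariate and −0.04 without sham control 2, where the test turned upward. Upward were endothelial markers (0.19, adjusted p = 8.72e-06, and adjusted p = 0.554 with an estimated correlation) and interferon genes (0.23, adjusted p = 0.0374, and adjusted p = 0.881 with an estimated correlation). So were hypoxia genes (0.17, adjusted p = 0.000628), smooth muscle markers (0.01, adjusted p = 0.0245) and skeletal muscle markers (0.88, adjusted p = 0.0304), each with an adjusted p = 0.734 with an estimated correlation. Among these only KCNJ8, a potassium channel of pericytes, passed over its list alone (0.44 ± 0.12). The glucocorticoid list did not pass (adjusted p = 0.597), but over the list alone CEBPD (1.52 ± 0.42) and DUSP1 rose and GLUL (−0.90 ± 0.23) and MAOA (−0.69 ± 0.23) fell. With the prefix as a covariate the hypoxia and interferon medians turned to −0.14 and −0.71. The medians without a fetus are in brackets, and those that moved did so by over 1.5 times. Without sham control 0 calls ended for interferon genes (0.09) and skeletal muscle markers (0.86), and medians moved for immediate early genes (0.10) and smooth muscle markers (0.07). Without sham control 1 calls ended for fatty acid oxidation (−0.27), thyroid genes (−0.26) and smooth muscle markers (−0.01), and medians moved for interferon genes (0.59). Without sham control 2 calls ended for thyroid genes (−0.19), interferon genes (0.03) and lymphocyte markers (−0.04), and medians moved for immediate early genes (0.32) and smooth muscle markers (0.02). Without sham control 3 calls ended for fatty acid oxidation (−0.34), thyroid genes (−0.23), interferon genes (0.02), smooth muscle markers (−0.02) and skeletal muscle markers (0.62). Without sham IUGR 1 the call ended for thyroid genes (−0.26). Without sham IUGR 3 the call ended for thyroid genes (−0.26). Without demedullated control 0 the call ended for lymphocyte markers (−0.56), and medians moved for TCA cycle (−0.53), hypoxia (0.35) and interferon genes (0.39). Without demedullated control 1 calls ended for fatty acid oxidation (−0.16), hypoxia (−0.03), thyroid genes (−0.25), interferon genes (−0.25) and smooth muscle markers (0.02), and medians moved for oxidative phosphorylation (−0.22), immediate early genes (−0.02) and endothelial markers (0.12). Without demedullated control 2 calls ended for thyroid genes (−0.25) and skeletal muscle markers (−0.17), and medians moved for hypoxia (0.29), interferon genes (0.47) and smooth muscle markers (0.07). Without demedullated IUGR 1 calls ended for thyroid genes (−0.26) and lymphocyte markers (−0.70). The number of lists was 7 without sham control 3. UCP1 was at 1644 ± 688 FPKM (SD, n = 3) in demedullated controls (log2 fold change −1.11 ± 0.70, adjusted p = 0.706), and the thermogenic and adrenergic lists did not pass (adjusted p = 0.624 and 0.387).

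The comparison of demedullated IUGR with demedullated control fetuses gave the growth restriction effect without an adrenal medulla. At the preset correlation of camera, ribosomal protein genes were higher and progenitor and matrix genes lower as lists, with 0 members of the 3 past the threshold over the list alone. With an estimated correlation 0 of 34 lists passed (adjusted p = 0.560, 0.560 and 0.752). No gene passed (0 of 12851 in limma, 618 with an unadjusted p under 0.05 against 643 expected). The 6 genes with the smallest p, none passing, were GPT2, an alanine aminotransferase (34.1 ± 16.4 FPKM in demedullated control and 8.35 ± 2.85 in demedullated IUGR, SD, n = 3 each), NGFRAP1 (29.6 ± 4.03 and 15.7 ± 1.05 FPKM), KLK10 (6.94 ± 0.751 and 1.31 ± 1.36 FPKM), PHPT1, a histidine phosphatase (413 ± 37.1 and 671 ± 100.1 FPKM), MATN4 (7.51 ± 1.40 and 3.16 ± 1.19 FPKM) and the retinol binding protein RBP1 (log2 fold change −1.22 ± 0.26, SE). Of the 7 lists that passed, 4 were upward, against 11 of 13 with TPM scaling, 2 of 7 with quantile scaling, 8 of 11 with the prefix as a covariate and 6 of 13 without the 3 libraries with liver transcripts. With quantile scaling the ribosomal protein median was −0.01, the oxidative phosphorylation median 0.04 and the TCA cycle median 0.03, none passing (adjusted p = 0.787, adjusted p = 0.280 and adjusted p = 0.286). Ribosomal protein genes had a median log2 fold change of 0.32 (22 of 23 higher, adjusted p = 8.76e-11, and adjusted p = 0.560 with an estimated correlation). The others were oxidative phosphorylation (0.27, 51 of 53 higher, adjusted p = 4.17e-07), TCA cycle (0.21, adjusted p = 0.0143) and interferon response (0.64, adjusted p = 0.00291), each with an adjusted p = 0.844 with an estimated correlation. Progenitor markers (−0.45, 14 of 16 lower, adjusted p = 1.27e-06) and Schwann cell markers (−0.23, adjusted p = 0.00926) were downward, each with an adjusted p = 0.560 with an estimated correlation. Matrix genes were downward as well (−0.24, adjusted p = 7.1e-06, and adjusted p = 0.752 with an estimated correlation). SFRP2 had a log2 fold change of −1.74 ± 0.63 (SE), COL3A1 −0.59 ± 0.27 and MPZ, a myelin protein and the only member past the threshold over its list alone, −0.93 ± 0.26. Of the 7 list calls 4 held with each fetus left out: ribosomal proteins, oxidative phosphorylation, progenitor markers and matrix genes. The medians without a fetus are in brackets, and those that moved did so by over 1.5 times. Without demedullated control 0 the call ended for interferon genes (0.47), and medians moved for TCA cycle (0.42) and matrix genes (−0.11). Without demedullated control 1 calls ended for TCA cycle (0.02) and Schwann cell markers (−0.15), and medians moved for oxidative phosphorylation (0.14) and interferon genes (1.26). Without demedullated control 2 the call ended for interferon genes (0.38), and medians moved for matrix genes (−0.38) and Schwann cell markers (−0.46). Without demedullated IUGR 0 the call ended for TCA cycle (0.10), and medians moved for oxidative phosphorylation (0.17) and interferon genes (1.01). Without demedullated IUGR 1 medians moved for TCA cycle (0.40), oxidative phosphorylation (0.50), interferon genes (0.98) and Schwann cell markers (−0.49). Without demedullated IUGR 2 calls ended for TCA cycle (0.14), interferon genes (−0.01) and Schwann cell markers (−0.18), and medians moved for oxidative phosphorylation (0.17) and progenitor markers (−0.30). The number of lists was 11 without demedullated control 0 or demedullated control 1 and 12 without demedullated IUGR 1. UCP1 did not pass (log2 fold change 0.78 ± 0.75).

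The interaction set growth restriction in demedullated fetuses, milder by weight, against that in sham fetuses. Cholesterol synthesis genes differed most clearly: 12 of 19 passed upward when adjusted over the list alone, with a median of 0.86 on the log2 scale (adjusted p = 7.9e-16 in camera, and adjusted p = 0.219 with an estimated correlation). SREBF2 was at 73.9 ± 8.31 FPKM in sham control and 44.7 ± 5.06 in sham IUGR (SD, n = 4 each) but at 53.4 ± 8.16 in demedullated control and 59.0 ± 5.54 in demedullated IUGR fetuses (n = 3 each), an interaction of 0.86 ± 0.19 (SE). It was 1.49 ± 0.37 for MSMO1, 1.54 ± 0.42 for SQLE (squalene epoxidase) and 0.98 ± 0.27 for STARD4. With the prefix as a covariate 0 members passed, and the interaction of the list mean was 0.72 ± 0.41 (SE) against 0.94 ± 0.27 without it. No gene passed over all genes (0 in limma, 523 with an unadjusted p under 0.05 against 643 expected). Besides SREBF2, the smallest p-values, none passing, were those of KLK10 (−2.29 ± 0.49), CEBPD, a transcription factor induced by glucocorticoids (−2.48 ± 0.59), ASGR2 (−2.54 ± 0.62), PHPT1 (0.73 ± 0.18) and GYG2, a glycogenin (−1.78 ± 0.44).

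Another 8 lists passed in the interaction, 2 upward and 6 downward. With cholesterol synthesis the balance was 3 upward and 6 downward. It was 3 and 3 with median-of-ratios, quantile or TPM scaling, and 6 and 2 with the prefix as a covariate. Progenitor markers had a median of 0.51 (adjusted p = 0.0108, with an estimated correlation adjusted p = 0.787), led by TCF21 (1.28 ± 0.52, SE), and interferon genes 1.07 (adjusted p = 0.00204, with an estimated correlation adjusted p = 0.787). Immediate early genes had a median of −0.33 (adjusted p = 0.00107, with an estimated correlation adjusted p = 0.219), with C-FOS at −1.98 ± 0.55. Hypoxia genes were at −0.36 (adjusted p = 0.00107), glycolysis genes at −0.24 (adjusted p = 0.0200) and macrophage markers at −0.25 (adjusted p = 0.0430). Heat shock genes were at −0.07 and ribosomal protein genes at −0.08 (adjusted p = 0.0443 for both). These 5 lists each had an adjusted p = 0.787 with an estimated correlation. Over lists that did not pass, CEBPD (glucocorticoid and adipocyte differentiation) and STAR (adrenal cortex, −3.38 ± 1.15) were lower over the list alone. The hypoxia median was 0.08 with the prefix as a covariate. None of these 8 calls held with each fetus left out, whereas that of cholesterol synthesis did. The medians without a fetus are in brackets, and those that moved did so by over 1.5 times. Without sham control 0 the call ended for heat shock (−0.07), and medians moved for glycolysis (−0.15) and ribosomal proteins (−0.12). Without sham control 1 the call ended for interferon genes (0.60), and medians moved for heat shock (−0.18) and macrophage markers (−0.47). Without sham control 2 calls ended for glycolysis (−0.19), heat shock (−0.01) and ribosomal proteins (0.02). Without sham control 3 calls ended for heat shock (−0.08) and macrophage markers (−0.03). Without sham IUGR 0 calls ended for glycolysis (−0.23), heat shock (0.01), interferon genes (0.95), ribosomal proteins (−0.04) and progenitor markers (0.41). Without sham IUGR 1 calls ended for glycolysis (−0.23), hypoxia (−0.16), ribosomal proteins (−0.06) and macrophage markers (−0.20), and medians moved for heat shock (−0.14). Without sham IUGR 2 the call ended for ribosomal proteins (−0.08), and medians moved for heat shock (−0.14) and macrophage markers (−0.51). Without sham IUGR 3 the call ended for macrophage markers (−0.04), and medians moved for heat shock (−0.15). Without demedullated control 0 calls ended for heat shock (0.0044) and interferon genes (0.90), and medians moved for macrophage markers (−0.73). Without demedullated control 1 calls ended for glycolysis (−0.02), hypoxia (−0.02), heat shock (−0.13), immediate early genes (−0.17) and macrophage markers (0.27), and medians moved for ribosomal proteins (−0.18). Without demedullated control 2 calls ended for heat shock (−0.03), interferon genes (0.72), ribosomal proteins (0.04) and progenitor markers (0.33). Without demedullated IUGR 0 the call ended for macrophage markers (−0.16), and medians moved for heat shock (−0.13). Without demedullated IUGR 1 calls ended for glycolysis (0.03), hypoxia (−0.03), heat shock (−0.03), ribosomal proteins (0.0044) and progenitor markers (0.30), and medians moved for immediate early genes (−0.18). Without demedullated IUGR 2 calls ended for heat shock (−0.02), interferon genes (0.36), ribosomal proteins (−0.08) and macrophage markers (−0.27), and medians moved for hypoxia (−0.59). The number of lists was 4 without sham IUGR 0 or demedullated control 1 and 5 without demedullated control 2 or demedullated IUGR 2.

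**Figure D3:**
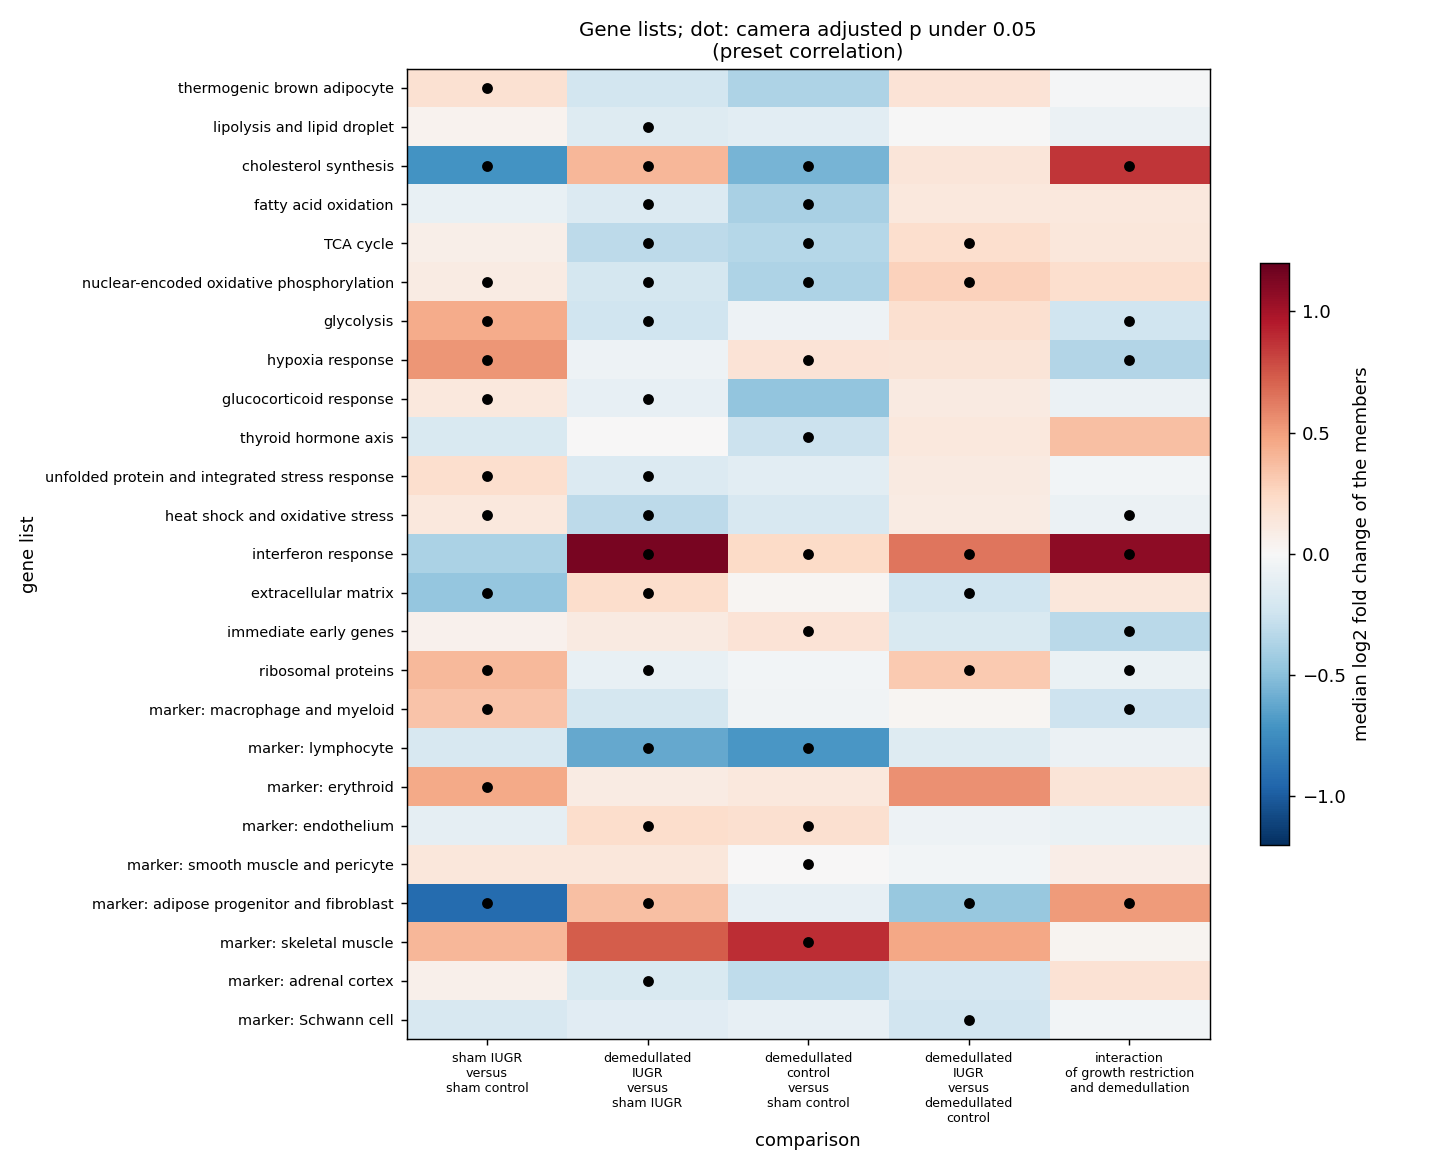
Median log2 fold change of the members of each gene list (colour, blue lower and red higher) in the 5 comparisons (columns), for the lists that passed camera in any of them; a dot marks an adjusted p under 0.05 at the preset correlation. Cholesterol synthesis stands at −0.71 in sham IUGR against sham control and at 0.86 in the interaction.

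Across all 12851 genes, which are not independent replicates, the growth restriction effect in sham fetuses correlated with that in demedullated fetuses with a Pearson r of 0.273 (Spearman rho 0.394, covariance 0.0486). These effects share no library, and 100 simulated data sets without any effect gave an r from −0.0791 to 0.0730. The simulated noise was independent between genes, whereas genes of a fetus vary together, so that range is too narrow to judge the r. The jackknife SE of the r over fetuses was 0.184. With the prefix as a covariate the r was −0.0940. Of the 10 genes called in sham fetuses, 9 had the same sign in demedullated fetuses, against 61.3% of all genes, and of the 199 genes at an adjusted p under 0.1 it was 168. The growth restriction effect in sham fetuses and the demedullation effect in IUGR fetuses had an r of −0.548, but both use the sham IUGR libraries, and simulated data without effects gave a mean r of −0.461 (range −0.525 to −0.402). That range rests on the same independent noise and is too narrow as well, and the jackknife SE of this r over fetuses was 0.187. The covariance was −0.0977 against −0.0592 in the simulated data. When the sham IUGR fetuses were split between the effects, 2 for each, the mean r over 6 splits was −0.162, from −0.217 to −0.0133.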

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

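The tests of the prefix on list means, of scaling, of endothelial against progenitor markers and of the libraries with liver transcripts were chosen only after the result was seen, and the other splits of the samples before.

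Cholesterol synthesis genes were lower in sham IUGR than in sham control fetuses, and their growth restriction effect differed between sham and demedullated fetuses, with a median interaction of 0.86 on the log2 scale (with an estimated correlation, adjusted p = 0.261 in sham fetuses and adjusted p = 0.219 for the interaction). The count of 16 members adjusted over the list alone was reached by 1 of 35 splits of the 8 sham fetuses, the real one, with at most 10 in another split. As 1 of 35 is the smallest share possible and the many counts split were not corrected for, chance is not excluded for it. The count of 12 in the interaction was reached by 1 of 100 shuffles of all group labels, the real one, with at most 5 in another. Those shuffles also remove the effects of growth restriction and demedullation. They thus do not test the interaction alone and do not exclude chance for it. The fit with the prefix as covariate cannot judge it, taking 1 prefix effect for all groups. Prefix 12 minus 11 was −0.38 in sham and 0.09 in demedullated IUGR fetuses. The list mean was −0.68 ± 0.24 (SE) with the covariate and −0.80 ± 0.18 without, with 4 and 16 members past the threshold. The tables argued against scaling. At the scaling nearest 0 the list median minus that of all genes was −0.63 (SE of the list mean at most 0.15). The values argued likewise against the libraries with liver transcripts, as the list median was −0.65 without them, with an SE of the list mean of 0.19. An effect of growth restriction stays open, as a hypothesis only. For the interaction the prefix stays open (list mean 0.72 ± 0.41 with the covariate and 0 members passing, 0.94 ± 0.27 without). So does the milder restriction of demedullated IUGR fetuses, which was not tested.

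Progenitor and fibroblast markers were lower in sham IUGR fetuses (with an estimated correlation, adjusted p = 0.261), with a median interaction of 0.51 (adjusted p = 0.787) whose call ended without sham IUGR 0 (0.41), demedullated control 2 (0.33) or demedullated IUGR 1 (0.30). The count of 13 members adjusted over the list alone was reached by 1 of 35 splits, the real one, with at most 4 in another. As 1 of 35 is the smallest share possible and the many counts split were not corrected for, chance is not excluded. The covariate fit (list mean −0.93 ± 0.24, SE) cannot judge the prefix, whose effect was 0.38 in sham and −0.52 in demedullated IUGR fetuses. The tables argued against scaling. At the scaling nearest 0 the list median minus that of all genes was −0.85 (SE of the list mean at most 0.24). A lower share of every cell type other than adipocytes would lower endothelial markers alike, but these lay above progenitor markers by 0.89 ± 0.19 in the difference between groups. The fall was not uniform, as the progenitor markers DPP4 and DPT overlapped between the groups and several members are matrix genes. Fewer progenitors or less expression in each may both account for the values, and the 2 were not tested apart.

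Other interaction medians were 1.07 for interferon genes, −0.24 for glycolysis, −0.36 for hypoxia, −0.0682 for heat shock, −0.33 for immediate early genes, −0.0814 for ribosomal proteins and −0.25 for macrophage markers, each tested as a difference in growth restriction effect between sham and demedullated fetuses. With an estimated correlation 0 of these 7 passed (adjusted p = 0.219 for immediate early genes and adjusted p = 0.787 for the other 6), and each call ended without at least 1 single fetus, named in the report. The interferon call ended without demedullated IUGR 2 (0.36), sham control 1 (0.60), demedullated control 2 (0.72), demedullated control 0 (0.90) or sham IUGR 0 (0.95). A single fetus stood far from the other 3 of its group in 6 of 72 groups tested, where chance gives about 1 in 20. By the gap divided by the range, these were sham control 1 for the scores of interferon (0.992), glycolysis (0.931) and unfolded protein response genes (0.832), sham IUGR 0 for IGFBP5 (0.902), sham control 3 for ALOX15 (0.879) and sham IUGR 2 for UCP1 (0.897). The interferon score was 1.27 in sham control 1 and −0.56 on average in the other 3 sham controls.

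For other results the same samples were split in other ways. In sham IUGR against sham control, the 10 changed genes were reached by 1 of 35 splits (at most 2 in another). The 13 matrix genes were reached by 1 of 35 (at most 6) and the 14 ribosomal protein genes by 1 of 35 (at most 0). No other split reached these counts, but 1 of 35 is the smallest share possible and the many counts were not corrected for. Chance cannot be excluded for them, nor for the 1944 genes at an unadjusted p under 0.05 (2 of 35 splits, up to 2302) or the 13 lists (10 of 35, up to 17). In demedullated control against sham control, only the real split reached the 6 immediate early genes (1 of 35 splits, at most 1 in another). That split is also the split by prefix, and with the prefix as a covariate 0 members passed. The count was 1 without sham control 0, demedullated control 1 or demedullated control 2. Chance cannot be excluded for the 6 genes, the 897 genes (4 of 35, up to 1702) or the 12 lists (10 of 35, up to 16). In demedullated against sham IUGR it cannot be excluded for the 805 genes (13 of 35, up to 1498) or the 16 lists (4 of 35, up to 23). The split of those 7 fetuses by prefix gave 1334 genes, above the real 805, but a split that mixed the prefixes gave 1498 and another 1323, so these counts do not single out the prefix. In the interaction, where all 4 group labels were shuffled, chance cannot be excluded for the 523 genes (40 of 100, up to 2565) or the 9 lists (69 of 100, up to 19). For demedullated IUGR against demedullated control the 10 splits are too few for a share under 0.05: the real values were 618 genes (6 of 10 splits, up to 1690) and 7 lists (10 of 10, up to 15).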

How the results depend on the processing

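Of the settings here, the fits without the 3 libraries with liver transcripts and without loci under 300 bp were chosen only after the result was seen. The relative depth differed by 1.69 times between libraries and the absolute depth is unknown, so low values carry no counting interval. Among 1927 results for called lists under an alternative, the test kept its direction and side of the threshold in 1561, kept the direction only in 353 and turned in 13. The median of the list turned in 32, in 22 of them while the test kept its direction. Where a value moved and no reason is given, the cause was not tested.

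With camera at an estimated correlation 0 lists passed in any of the 5 comparisons (13, 16, 12, 7 and 9 at the preset correlation), and with fry 3 passed in sham IUGR against sham control and 0 in the others. The 10 genes of sham IUGR against sham control became 5 with no filter (more genes tested), 4 with median-of-ratios or quantile scaling, 6 without a trend, 590 with robust array weights (124 higher, 466 lower), 25 with only the 2 groups, 3 with sex as a covariate or without the female fetus, 0 with the prefix as a covariate, 0 without the 3 libraries with liver transcripts (fewer samples) and 199 at an adjusted p of 0.1. Cholesterol members (16) became 4 with the prefix, matrix members (13) 7 with median-of-ratios scaling and 6 with the prefix (5 lower and 1 higher). Ribosomal members (14) became 8 with log2(FPKM + 0.01), 0 with no filter, 2 with quantile or TPM scaling, 0 with the prefix and 0 without the 3 libraries. In limma, 1 gene instead of 0 changed in demedullated against sham IUGR without a trend, with robust weights, with sex as a covariate, without the female fetus, at an adjusted p of 0.1 and without the 3 libraries, and in demedullated IUGR against demedullated control with no filter, with robust weights, with only the groups and without the 3 libraries. The unadjusted counts are in the report.

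The lists past the threshold became 10 in demedullated against sham IUGR with quantile scaling, with sex as a covariate and without the female fetus (16). They became 13 in demedullated IUGR against control with TPM scaling, 11 with robust weights or the prefix and 13 without the 3 libraries (7), and in the interaction 5 with no filter, 14 with age as a covariate and 16 without the 3 libraries (9). With the prefix 0 immediate early genes passed in demedullated against sham control (6) and 0 cholesterol genes in the interaction (12). Lists whose test turned were adrenal cortex in demedullated against sham IUGR (0.0132 with no filter), oxidative phosphorylation in sham IUGR (−0.0346 with quantile scaling) and lymphocyte markers in demedullated control (−0.0287 with age, −0.0438 without sham control 2). With the prefix, hypoxia (−0.136) and interferon (−0.705) turned in demedullated control, hypoxia in the interaction (0.0799), and the correlation of effects across genes (−0.0940). Without demedullated control 1, interferon was −0.251 in demedullated control and macrophage markers 0.272 in the interaction. Without demedullated IUGR 1, oxidative phosphorylation was 0.0338 and glycolysis 0.0684 against sham IUGR. Without demedullated IUGR 2, interferon was −0.0081 against demedullated control. Without the 3 libraries the unfolded protein response was −0.0141 in demedullated against sham IUGR. Medians that turned while the test kept its direction were, apart from single fetuses, thermogenic genes in sham IUGR (−0.0001 with no filter), the unfolded protein response in sham IUGR (−0.0001 without the 3 libraries), smooth muscle in demedullated control (−0.0280 with robust weights, −0.0336 with the prefix), skeletal muscle in demedullated control (−0.203 with a minimum mean of 5 FPKM), TCA cycle (−0.0394 with TPM scaling) and ribosomal proteins (−0.0124 with quantile scaling) in demedullated IUGR against control, and heat shock (0.0365) and ribosomal proteins (0.0215) in the interaction with age. With the sham IUGR fetuses split 2 and 2 the opposition of effects was −0.162, since no library was then shared.

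Of 57 list calls 20 held with each fetus left out. With each fetus left out in turn, sham IUGR against sham control gave 0 to 234 genes, 11 to 15 lists, 9 to 18 cholesterol, 10 to 13 progenitor, 5 to 14 matrix and 1 to 16 ribosomal members. Demedullated against sham IUGR gave 0 to 2 genes in limma (1 without sham control 1, sham IUGR 2, sham IUGR 3 or demedullated IUGR 0, and 2 without demedullated IUGR 2) and 10 to 20 lists. Demedullated against sham control gave 0 to 1 genes (1 without demedullated control 2 or demedullated IUGR 1), 7 to 14 lists and 1 to 6 immediate early members. Demedullated IUGR against control gave 0 to 2 genes (1 without sham control 1, sham IUGR 2 or demedullated control 2, and 2 without demedullated IUGR 2) and 7 to 12 lists, and the interaction 0 to 2 genes (1 without sham IUGR 2 or demedullated control 2, and 2 without demedullated IUGR 2), 4 to 11 lists and 8 to 14 cholesterol members. Medians of lists whose test turned when 1 fetus was left out ranged from −0.328 to 0.0338 (oxidative phosphorylation) and −0.378 to 0.0684 (glycolysis) in demedullated against sham IUGR, −0.251 to 0.591 (interferon) and −0.965 to −0.0438 (lymphocyte) in demedullated against sham control, −0.0081 to 1.26 (interferon) in demedullated IUGR against control and −0.731 to 0.272 (macrophage) in the interaction. Medians that turned while the test kept its direction ranged from −0.0141 to 0.189 (oxidative phosphorylation) and −0.0001 to 0.291 (unfolded protein response) in sham IUGR, −0.0294 to 0.347 (hypoxia), −0.0177 to 0.315 (immediate early genes), −0.0161 to 0.0726 (smooth muscle) and −0.169 to 1.24 (skeletal muscle) in demedullated control, and −0.350 to 0.0294 (glycolysis), −0.177 to 0.0146 (heat shock) and −0.177 to 0.0365 (ribosomal proteins) in the interaction. The correlation of effects lay between 0.182 and 0.342 and their opposition between −0.625 and −0.387.

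With the replicate number as a block 0 genes passed in sham IUGR against sham control and 7 ribosomal members, with 3 residual degrees of freedom fewer. The labels do not say that equal numbers pair fetuses: 19 same-number pairs had a median r of −0.0229 (−0.235 to 0.212) after centring, against −0.0164 for other pairs, 2 of the 19 exceeded 0.1, and 2 of 14 fetuses matched best their own number.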

Other observations

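The tests in this part, of liver transcripts and of UCP1 with other genes, lists, weight and age, were chosen only after the result was seen.

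UCP1 varied widely between fetuses of a group, from 638 to 8247 FPKM over all. FKBP5, a gene that glucocorticoids induce, was picked after its values and those of PDK4 and GPX3 had been seen beside those of UCP1, so their r with UCP1 cannot support an explanation (for FKBP5 0.751 on log2 levels centred within groups, 0.769 among the 7 fetuses of prefix 11 and 0.825 among the 7 of prefix 12). Of the other 16 tested genes in the glucocorticoid list, which was written before the data were examined, 6 had a permutation adjusted p under 0.05 over these 16, 4 with a positive r and 2 with a negative one. TSC22D3 had an r of 0.409 and SGK1 of 0.060, neither passing, and weight had one of −0.577 and gestational age of −0.113. The score of these 16 genes had an r of 0.9 with UCP1, but the scores of thermogenic genes (0.856, with UCP1 among them), oxidative phosphorylation (0.827), TCA cycle (0.811) and fatty acid oxidation (0.738) passed over 34 lists as well. Glucocorticoid exposure of the fetus therefore cannot be told apart from a wider difference in brown fat genes between fetuses, since no exposure was measured.

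Transcripts of liver were high in sham IUGR 2, demedullated control 0 and demedullated IUGR 0, each from a different group. AHSG was at 1530, 244 and 202 FPKM there and at most 10.4 in the other 11, and ALB (albumin) at 183, 35.3 and 68.8 FPKM against up to 82.3 elsewhere. The log levels of 30 such transcripts correlated between the 3 libraries with an r of at least 0.925, and with any other library of at most 0.791. RNA from liver could bring this, but 23 of the 30 lay above all others in all 3, and it cannot be told apart from expression in the depot, since the libraries were picked for these transcripts and 7 of the 30 did not stand above the rest. No biological explanation was tested.

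STAR was at 141 FPKM in sham IUGR 0 and 103 in sham IUGR 3 and between 5.42 and 37.8 FPKM in the other 12 fetuses.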
